A study of Homo sapiens with 12 samples.

How the data were processed

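Gene expression was measured in A549 cells, an established human lung carcinoma line, with Illumina bead arrays that carry 47323 probes in the deposited scanner table. Per the labels, cells received the vehicle DMSO (0.01%), 10 nM TCDD, 10 µM CH223191 or TCDD together with CH223191 for 6 h, and total RNA was labelled with biotin. The labels give no separate doses for the combination. There were 12 arrays, 3 per group. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

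The deposited scanner table holds, per the file headers, an average bead intensity on a linear scale and a detection p-value for each probe and array. Its intensity values are not normalized between arrays. The authors' processed table holds 47319 probes as intensity without a log. Its scale and processing are not stated in the sources used here. Set against the scanner table, each of its columns had a Spearman correlation of 1 with the same array, and its sorted values differed from the mean of the sorted scanner columns by a median of 0.00400% and at most 0.891%, which is what quantile normalization without background subtraction gives. The median of each of its 12 columns was 99.3 intensity units. It was used as an alternative, on a log2 scale. No scanner software, chip position or scan date is given in the sources used here.

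Intensities were corrected for background by normexp with the noise taken from the detection p-values, an offset of 16 was added, arrays were quantile-normalized and values put on a log2 scale, with limma 3.58.1 in R 4.3.3. Probes with a detection p-value under 0.05 on at least 3 arrays were kept, 13331 in all. Probe names came from the platform annotation table supplied with the series, in which 30112 probes have 1 gene symbol, 8 have several and 17203 have none. Symbols were updated through the Entrez number for 30073 of them, with the RefSeq gene table of assembly GRCh38.p14. Of the detected probes, 9904 had 1 symbol and 3427 had none that could be used, and these unnamed probes entered only a fit of every detected probe. Each gene was represented by its detected probe with the highest mean over the 12 arrays, which left 8366 genes, 1338 of them with more than 1 detected probe. No coordinates are given because no genome build for the array is named in the sources used here.

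One linear model with a mean per group was fitted to all 12 arrays with lmFit and eBayes, two-sided, with 8 residual degrees of freedom and a prior worth 6.18 more. The contrasts were TCDD, CH223191 and the combination against DMSO, the combination against TCDD and against CH223191, and the interaction, which is the TCDD effect with CH223191 minus that without it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The median residual SD was 0.22 on the log2 scale. The median 95% confidence interval reached 0.38 log2 units to either side for a comparison of 2 groups and 0.54 for the interaction, and the number of arrays limits this precision. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so p-values were taken from limma, and splits of the arrays were only counted.

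Gene lists were fixed before the data were examined, 26 in number, and 25 had at least 2 tested members. The list of liver and breast line markers had 1 and was not tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which does not compare a list with other genes, were alternatives. A list's shift is the mean log2 change of its tested members minus that of the other genes. Genes were also adjusted over the list alone. That adjustment does not correct for the number of lists or of comparisons, so some genes can pass it by chance. Where a probe was not detected on any array of a group, a fold is given as a lower bound, from the bright group's mean against the mean, per array, of the higher of the lowest normalized signal among detected probes and the probe's own. Such a bound compares means and carries no sampling error, so it does not by itself show a difference.

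The rule for named genes was fixed at the same time. It took the called genes with the largest change whose arrays of one group all lay on the same side of the other's, up to 12 per direction against DMSO and up to 6 in the other contrasts (in the interaction without the condition on arrays), leaving out symbols that are only locus, cluster or open reading frame names. It also took every measured member of the AhR battery, AHR itself, and up to 4 members with the largest change in each other list. Genes named outside this rule are said to be chosen after their values were seen.

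The fit and the list test were checked on simulated arrays made from the gene means and spreads of these data, with 200 of 8366 genes changed. In the simulated TCDD vs DMSO comparison, 34% of genes changed by 1.5-fold, 84% of those changed by 2-fold and 96% of those changed by 3-fold were recovered, and 5 unchanged genes were among 160 called. In the simulated comparison of CH223191 with DMSO, 34%, 80% and 98% were recovered at those sizes, and in that of the combination with TCDD 26%, 76% and 92%. The Benjamini-Hochberg threshold is stricter when fewer genes change. These shares therefore overstate recovery where few genes change, and a count of 0 does not exclude changes of these sizes. A shift of 0.35 of the 13 tested genes of the ATF4 list was called by camera in each of these simulated comparisons, with 0 other lists called. The simulated genes varied independently of each other. The check therefore does not show how camera fares when the genes of a list are correlated.

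Alternatives planned beforehand were no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed table, no detection filter, a stricter filter (detection p under 0.01 on all 12 arrays), the average of a gene's probes, every detected probe as the unit, only the 2 groups compared in the fit, the replicate number as a block, eBayes with trend and robust, array weights, a minimum of 1.5-fold, the list tests named above, and each array left out in turn with normalization and the choice of probe repeated. No background correction together with trend and robust was added after seeing the data. Figures were drawn with matplotlib 3.10.9.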

Results

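Expression was profiled in A549 cells treated for 6 h with vehicle, with the aryl hydrocarbon receptor (AhR) agonist TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin), with CH223191, a synthetic AhR antagonist, or with both. Each group had 3 arrays. Between 10314 and 11880 of the 47323 probes were detected per array (21.8% to 25.1%), and median raw intensity lay between 92.8 and 102.9 units. Across genes, arrays of one group correlated at 0.972 to 0.979 and arrays of different groups at 0.970 to 0.978, and no pair of arrays held identical values. AHR, which encodes the receptor, was detected on all 12 arrays, with raw means between 268 and 292 in the 4 groups. Its log2 change with TCDD was -0.12 ± 0.14 (SE, adjusted p = 0.964).

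The first comparison asked what the agonist does alone. The AhR battery, a list of genes known as direct targets of the receptor, rose with TCDD on average. Its 8 tested members shifted by 0.36 log2 units against other genes (camera adjusted p = 0.000333, and adjusted p = 0.0496 with an estimated correlation). TIPARP and CYP1B1 made up most of the shift, and 7 of the 8 members had positive changes. The largest was that of TIPARP, a mono-ADP-ribosyltransferase that restrains AhR signalling, at a fitted 1.41 ± 0.21 (SE), or 2.66-fold (limma adjusted p = 0.0821). CYP1B1, a cytochrome P450 of xenobiotic and estrogen metabolism, had a difference of 0.86 ± 0.16 (adjusted p = 0.145) and SLC7A5, an amino acid transporter, 0.43 ± 0.14 (adjusted p = 0.863). In each of these genes all 3 TCDD arrays lay above all 3 DMSO arrays, and TIPARP and CYP1B1 were detected on 2 of the 3 DMSO arrays. CYP1B1 was not detected on any array with CH223191, so it passed the detection filter only through its 3 TCDD arrays. Adjusted over the list alone, these 3 genes passed, with adjusted p of 7.88e-05, 0.000416 and 0.0192. Estimated log2 differences were 0.26 ± 0.13 for CYP2S1, 0.19 ± 0.12 for NQO1, 0.06 ± 0.20 for HES1, 0.03 ± 0.12 for ALDH3A1 and -0.32 ± 0.25 for NEDD9, and none of the 5 passed either adjustment. These small differences moved with single arrays: NEDD9 was -0.10 and CYP2S1 0.17 without DMSO replicate 2, and leaving out an array gave -0.47 to -0.10 for NEDD9, 0.17 to 0.33 for CYP2S1, -0.07 to 0.30 for HES1 and -0.02 to 0.09 for ALDH3A1. The sizes depended on the background: without its correction TIPARP differed by 0.56 and was called, as in 9 of 24 settings, CYP1B1 differed by 0.30 and the list shifted by 0.20. The list's shift was 0.17 with no detection filter, where it was still called, and 0.21 with detection p under 0.01 required on all 12 arrays, where its call was lost (adjusted p = 0.0593, and 6.79e-06 to 0.0496 in the other settings). That stricter filter leaves out TIPARP and CYP1B1.

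CYP1A1, the textbook AhR target, was not detected on any array. Its 1 probe read 94.3 ± 7.47 raw units (SD, n = 3) with DMSO, 93.8 ± 3.96 with TCDD, 95.9 ± 4.34 with CH223191 and 94.2 ± 5.74 with the combination. The probes of CYP1A2, AHRR, UGT1A1, ABCG2 and XDH were likewise not detected on any array. UGT1A6 and NFE2L2 were detected on at most 1 array and SERPINB2 had no named probe, so 8 of the battery's 17 members were tested.

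**Figure D1:**
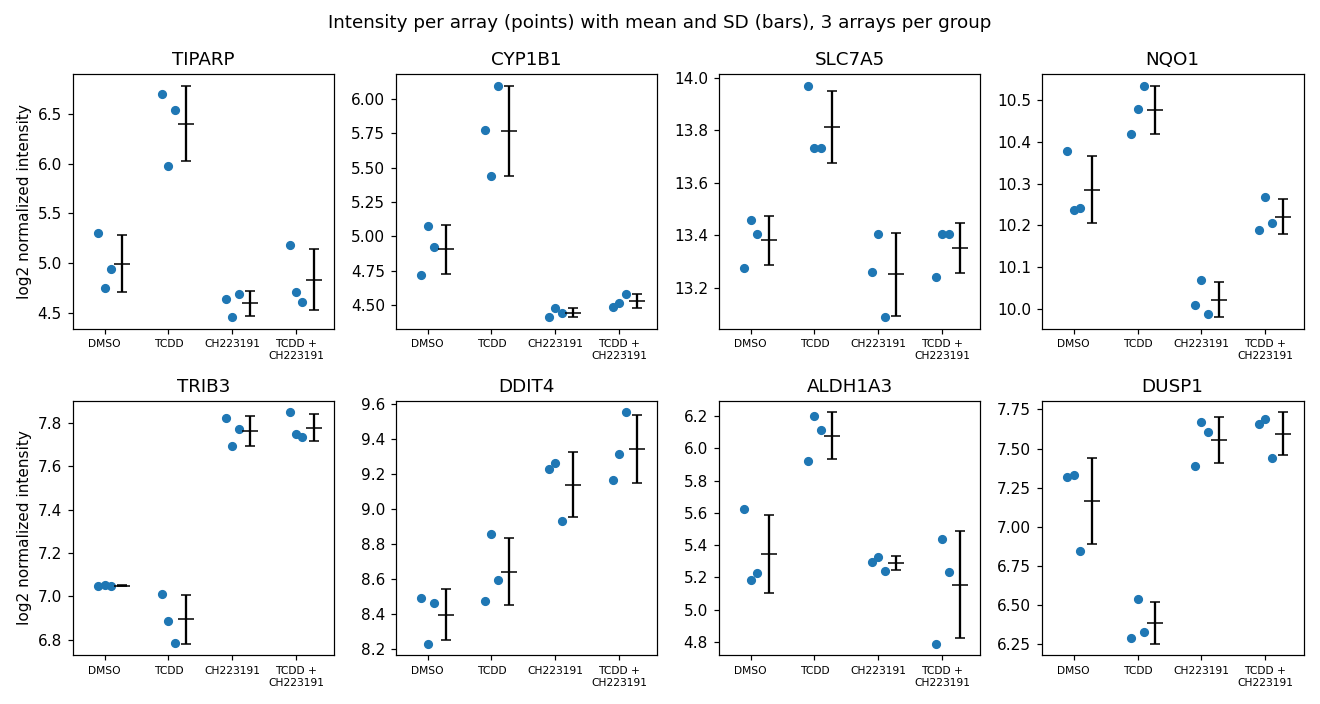
Normalized log2 intensity (vertical axis, with a separate range in each panel that does not start at 0) of 8 genes by treatment group (horizontal axis). Points are the 3 arrays of a group, and the bar beside them is their mean and SD. TIPARP and CYP1B1 were highest on the TCDD arrays, where TIPARP averaged 1.41 above DMSO, and TRIB3 was higher on all arrays with CH223191 than on all others.

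No single gene passed the adjusted threshold in TCDD vs DMSO: limma called 0 of 8366 genes, with 422 (5.04%) at an unadjusted p under 0.05, where chance gives 5%. Other settings called between 0 and 9, and 1 gene was called without DMSO replicate 2 (SNORD139, adjusted p = 0.0239) and 1 without TCDD replicate 2 (TIPARP, adjusted p = 0.0221). Among genes with the smallest p, chosen after their values were seen, SNORD139 had a difference of 0.99 ± 0.16 and UBASH3B of 0.84 ± 0.14 (adjusted p = 0.0821 for each), and MYH14 of -0.85 ± 0.15 and MEPCE of -1.05 ± 0.18 (adjusted p = 0.0831 for each). Within their own lists, DUSP1, a phosphatase of MAP kinases, was lower (-0.78 ± 0.16, adjusted p = 0.00348 when adjusted over the list alone), while IER3 (0.53 ± 0.13, adjusted p = 0.0104 among immediate early genes and 0.0192 among short-lived transcripts), the retinaldehyde dehydrogenase ALDH1A3 (0.73 ± 0.18, adjusted p = 0.00919) and the mucin MUC1 (0.61 ± 0.19, adjusted p = 0.0218) were higher. Over all genes none of these 4 passed, with adjusted p of 0.290, 0.563, 0.427 and 0.828. Without background correction SNORD139 differed by 0.36, MEPCE by -0.37, MYH14 by -0.38, DUSP1 by -0.45, ALDH1A3 by 0.45 and MUC1 by 0.21.

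The second comparison gave the effect of the antagonist alone. The list of ATF4 targets and unfolded protein response genes, which covers amino acid synthesis and stress signalling, rose with CH223191: its 13 tested members shifted by 0.34 (camera adjusted p = 2.31e-06, and adjusted p = 0.0119 with an estimated correlation), and 11 of them had positive changes. Adjusted over the list alone, 5 genes passed. Of these, TRIB3, a pseudokinase induced by ATF4, changed by 0.71 ± 0.12 (1.64-fold), DDIT4, an inhibitor of mTORC1, by 0.74 ± 0.16 and PPP1R15A, which directs dephosphorylation of eIF2 alpha, by 0.50 ± 0.14. The serine synthesis enzyme PSAT1 (0.43 ± 0.15) and the asparagine synthetase ASNS (0.39 ± 0.14) were the others, both chosen after their values were seen. The other detected ASNS probe had a difference of 0.12.

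NRF2 targets, genes of antioxidant defence, fell as a list with CH223191 by 0.13 (camera adjusted p = 0.0316), but adjusted p = 0.361 with an estimated correlation. Of its 19 tested members 13 had negative changes, and the heme oxygenase HMOX1 passed over the list alone (-0.58 ± 0.13, adjusted p = 0.00963). The call of the list was also lost with only these 2 groups in the fit (adjusted p = 0.0539) and without any 1 of DMSO replicates 1, 2 and 3 or CH223191 replicates 2 and 3, at adjusted p of 0.0808, 0.0541, 0.0738, 0.0636 and 0.135. The AhR battery shifted by -0.19 (adjusted p = 0.0552), with 7 of 8 members negative. Camera called the battery without background correction (shift -0.11, adjusted p = 0.0102) and without TCDD replicate 2 (shift -0.19, adjusted p = 0.0409), and gave adjusted p = 0.286 with an estimated correlation. Fry, which tests the members' own changes and not their difference from other genes, gave adjusted p = 0.00442 for the battery and adjusted p = 0.0590 for NRF2 targets. TIPARP and CYP1B1 were detected on 2 of 3 DMSO arrays and on no CH223191 array, so that only bounds on the means could be given. The means were at least 1.07-fold lower for TIPARP (limma adjusted p = 0.692) and at least 1.00-fold for CYP1B1 (adjusted p = 0.514). Neither gene was called, so a decrease was not shown.

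Gene by gene, limma called 0 of 8366 genes in CH223191 vs DMSO, with 631 (7.54%) at an unadjusted p under 0.05. Other settings called between 0 and 12. The smallest adjusted p, 0.0889, was shared by TRIB3 and by 3 genes chosen after their values were seen: the AMPK-related kinase NUAK2 (0.93 ± 0.14, with 0.18 for its other detected probe), the ferritin receptor of autophagy NCOA4 (-0.93 ± 0.15) and MYH14 (-0.86 ± 0.15). Over their lists alone, the matricellular gene CCN1 (0.73 ± 0.17), ID1 (0.42 ± 0.14, with 0.77 for its other detected probe) and LEF1 (at least 1.17-fold, as it was not detected with DMSO) were higher, and the heat shock gene HSPA1B (-0.98 ± 0.20), the transcription factor IRF1 (-0.71 ± 0.15) and LST1 (at least 1.30-fold, as it was not detected with CH223191) were lower. IFI6 passed with the probe used (0.58 ± 0.16), while its other detected probe had a difference of -0.07. None of these 7 passed over all genes. Without background correction 12 of 19 genes with a change of at least 0.3, among those compared over the settings, had one smaller by over 1.5 times, with NCOA4 at -0.62, MYH14 at -0.39, HSPA1B at -0.62, IRF1 at -0.40, HMOX1 at -0.36 and CCN1 at 0.36.

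With TCDD and CH223191 together, the ATF4 list again rose against DMSO, by 0.37 (camera adjusted p = 6.65e-08, and adjusted p = 0.00579 with an estimated correlation). Over the list alone 7 of its 13 members passed. DDIT4 changed by 0.95 ± 0.16 (1.93-fold), TRIB3 by 0.73 ± 0.12, XBP1, a transcription factor of the unfolded protein response, by 0.63 ± 0.19 and PSAT1 by 0.49 ± 0.15. PPP1R15A (0.45 ± 0.14), the serine synthesis enzyme PHGDH (0.44 ± 0.15) and ASNS (0.35 ± 0.14) were chosen after their values were seen. ASNS depended on the probe, since its other detected probe had a difference of -0.65 and the average of its probes gave -0.15. The AhR battery shifted by -0.09 (camera adjusted p = 0.718). TIPARP, detected on 1 of 3 arrays of the combination, had a fitted difference of -0.16 ± 0.21 (leaving out an array, -0.34 to -0.01). CYP1B1, not detected in the combination, was lower by at least 1.01-fold (limma adjusted p = 0.668). NRF2 targets shifted by -0.11 (adjusted p = 0.129). No gene was called by limma, 590 (7.05%) had an unadjusted p under 0.05, and other settings called between 0 and 9. Over their lists alone HMOX1 (-0.51 ± 0.13), IRF1 (-0.48 ± 0.15), HPGD (-0.46 ± 0.14) and AXIN2 (-0.56 ± 0.18) were lower and CCN1 (0.82 ± 0.17), IFI6 (0.56 ± 0.16, with 0.27 for its other detected probe) and ID1 (0.46 ± 0.14) higher. The ATF4 list's shift was 0.23 with no detection filter, where it was still called, and without background correction 10 of 18 genes compared over the settings with a change of at least 0.3 had one smaller by over 1.5 times, among them XBP1 (0.35), CCN1 (0.41), IFI6 (0.32), HMOX1 (-0.32), IRF1 (-0.28), HPGD (-0.24) and AXIN2 (-0.22).

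What the antagonist changed in cells given TCDD was read from the combination against TCDD alone, a comparison without DMSO arrays. TIPARP, detected on 1 of 3 arrays of the combination, fell by 1.57 on the log2 scale (SE 0.21, limma adjusted p = 0.00807), a fitted size and not a measured fold. CYP1B1 was lower by at least 1.84-fold, as it was not detected on any array of the combination (adjusted p = 0.00807). DUSP1 rose by 1.21 ± 0.16 (2.31-fold, adjusted p = 0.00807) and TRIB3 by 0.89 ± 0.12 (1.85-fold, adjusted p = 0.00860). These 4 were the genes limma called, 2 higher and 2 lower, and in each all 3 arrays of one group lay beyond all 3 of the other, which chance gives for 10% of genes. At an unadjusted p under 0.05 there were 538 (6.43%). The count depended on single arrays: it was 0 without TCDD replicate 1 or without TCDD replicate 3, and 1 without replicate 1 of the combination, and TIPARP was not called without replicate 3 of the combination (adjusted p = 0.0536). The log2 differences over the fits leaving out an array were -1.79 to -1.41 for TIPARP, -1.41 to -1.08 for the fitted signal of CYP1B1, 1.16 to 1.28 for DUSP1 and 0.83 to 0.94 for TRIB3. Without background correction the differences were smaller, at -0.62 for TIPARP, -0.46 for CYP1B1, 0.73 for DUSP1 and 0.58 for TRIB3, and 16 genes were called. Of 23 genes compared over the settings with a change of at least 0.3, 12 had one smaller by over 1.5 times. The count of called genes was also 0 with only these 2 groups in the fit and 2 with median scaling.

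Among gene lists in the same comparison, the AhR battery fell by 0.44 (camera adjusted p = 6.48e-06, and adjusted p = 0.0103 with an estimated correlation), where SLC7A5 fell by 0.46 over the list alone (adjusted p = 0.0124), and the differences of CYP2S1 (-0.26 ± 0.13) and NQO1 (-0.26 ± 0.12), also a member of the NRF2 list, did not pass. The battery's shift was -0.25 without background correction, -0.23 with no detection filter and -0.28 with the stricter one, and it was called in each. The ATF4 list rose by 0.34 (camera adjusted p = 3.66e-06, and adjusted p = 0.0103 with an estimated correlation). ATF4 itself changed by 0.95 ± 0.26, DDIT4 by 0.70 ± 0.16 and XBP1 by 0.58 ± 0.19, all within the 7 members that passed over the list alone. ASNS, chosen after its values were seen, was also among the 7 (0.51), but its other detected probe had a difference of -0.07 and the average of its probes gave 0.22. Without background correction ATF4 changed by 0.40 and XBP1 by 0.33, and the differences of HMOX1 and RDH10 were -0.25 and -0.26. NRF2 targets fell by 0.17 (camera adjusted p = 0.000686), but adjusted p = 0.178 with an estimated correlation, with 17 of 19 members negative. Among them the glutathione synthesis subunit GCLM (-0.50 ± 0.14), the thioredoxin reductase TXNRD1 (-0.47 ± 0.13) and HMOX1 (-0.40 ± 0.13) passed over the list alone. In the retinoid list, ALDH1A3 (-0.93 ± 0.18) and RDH10 (-0.65 ± 0.17) were lower over the list alone, while the list as a whole was not called (shift -0.13, adjusted p = 0.178). The other detected ALDH1A3 probe had a difference of -1.61. It represented the gene when any CH223191 array or replicate 2 or 3 of the combination was left out, and the gene was then called over all genes, at -1.61 to -1.48 (adjusted p of 0.00976, 0.00816, 0.00923, 0.0378 and 0.0304).

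**Figure D2:**
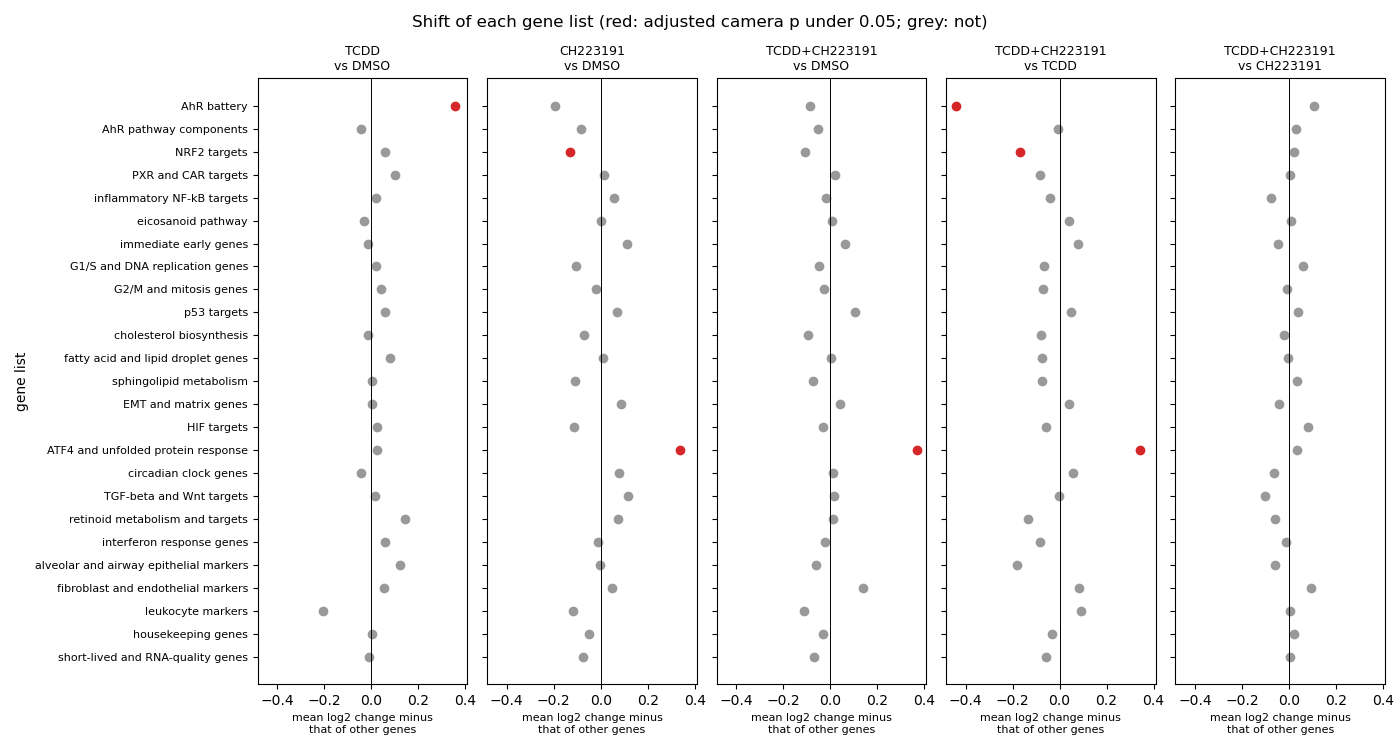
Shift of each of the 25 tested gene lists (vertical axis), as the mean log2 change of its members minus that of the other genes (horizontal axis, log2 units), in the 5 comparisons of 2 groups. Each point is a list, red where the adjusted camera p was under 0.05. The AhR battery lies at 0.36 in TCDD vs DMSO and at -0.44 in the combination against TCDD, and the ATF4 list between 0.34 and 0.37 in the 3 comparisons of CH223191 with no CH223191.

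The effect of TCDD in cells that also received the antagonist was read from the combination against CH223191 alone. CYP1B1 was not detected on any array of either group, and TIPARP was detected on 1 of 3 arrays of the combination and on none with CH223191 alone, so no fold is given for them. SLC7A5 had a difference of 0.10 (95% CI -0.20 to 0.39) and NQO1 of 0.20 (-0.06 to 0.46). The battery shifted by 0.11 (camera adjusted p = 0.996), and by 0.06 without background correction or with no detection filter. Limma called 0 genes, 453 (5.41%) had an unadjusted p under 0.05, and 0 were called under every alternative run. Across genes, which are not independent replicates, the TCDD effect with CH223191 had a correlation of 0.01 with that without it (leaving out an array, -0.01 to 0.04), from arrays that the contrasts do not share. In TCDD vs DMSO only 5.04% of genes had an unadjusted limma p under 0.05, where chance gives 5%. A correlation over all genes therefore cannot show whether CH223191 removed the TCDD effect. The ratio of the remaining to the original TCDD effect was not computed, because no gene was called in TCDD vs DMSO. The CH223191 effect with TCDD correlated at 0.12 with that without it (0.07 to 0.14).

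The difference between the TCDD effects with and without CH223191 was tested as an interaction. Limma called 0 genes, 430 (5.14%) had an unadjusted p under 0.05, and 0 were called under every alternative run. TIPARP had an interaction of -1.17 (95% CI -1.81 to -0.53, adjusted p = 0.709) and CYP1B1 of -0.78 (-1.27 to -0.29, adjusted p = 0.745), and both passed over the battery alone (adjusted p = 0.0120 and adjusted p = 0.0171). Their signals with CH223191 alone were at background, so these sizes are fitted values and not measured folds, and without background correction they were -0.47 and -0.25. DUSP1 (0.82 ± 0.23), ALDH1A3 (-0.87 ± 0.25) and MUC1 (-0.89 ± 0.26) passed over their own lists alone, and were 0.47, -0.46 and -0.30 without background correction. The battery's interaction shift was -0.25, or -0.12 with no detection filter, not called by camera (adjusted p = 0.245). Fry, on the members' own interaction, gave adjusted p = 0.00906.

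No gene was called in both TCDD vs DMSO and CH223191 vs DMSO. Their changes correlated at 0.484 across genes (leaving out an array, 0.414 to 0.609). Unchanged groups simulated as noise, with a shared control that was simulated too, gave 0.501, and the covariance exceeded the simulated one by 0.00417. Such a simulated correlation follows from equal groups sharing a control and holds no information on these DMSO arrays. TCDD and the combination correlated at 0.503 (0.413 to 0.624) against a simulated 0.500, with a covariance excess of 0.00467. The combination and CH223191 correlated at 0.570 (0.483 to 0.671) against a simulated 0.501, with a covariance excess of 0.0102. The jackknife SE of these 3 correlations was 0.202, 0.203 and 0.183. Leaving out an array makes the groups unequal in size, which by itself moves a correlation that rests on shared arrays. The SE and the ranges above therefore cannot decide whether a correlation differs from its simulated value. With 3 DMSO arrays the control could not be split into parts of at least 2 arrays, so part of any excess may come from the shared arrays.

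The other lists were not called by camera in any comparison, while fry, which makes no comparison with other genes, called HIF targets in CH223191 vs DMSO (adjusted p = 0.0476) and G2/M genes in the combination against TCDD (adjusted p = 0.0277). Of the liver and breast line markers only KRT7 was tested, at 0.10 with TCDD (adjusted p = 0.974). With TCDD, leukocyte markers shifted by -0.20 (adjusted p = 0.158), retinoid genes by 0.14, alveolar and airway markers by 0.12, PXR and CAR targets by 0.10, fatty acid and lipid droplet genes by 0.08, interferon response genes by 0.06, p53 targets by 0.06, NRF2 targets by 0.06, fibroblast and endothelial markers by 0.06 and G2/M genes by 0.04. AhR pathway components and circadian clock genes each shifted by -0.04 and eicosanoid genes by -0.03. NF-kB targets, G1/S genes, HIF targets, TGF-beta and Wnt targets and the ATF4 list shifted by 0.02 each. Cholesterol, immediate early, sphingolipid, EMT and housekeeping genes and short-lived transcripts lay between -0.015 and 0.0025. In 6 of these lists the median had the opposite sign to the shift: NF-kB targets (-0.01), TGF-beta and Wnt targets (-0.03), EMT genes (-0.09), AhR pathway components (0.01), eicosanoid genes (0.04) and cholesterol genes (0.01). Camera's direction was also opposite for the TGF-beta and Wnt, EMT and cholesterol lists. With CH223191, immediate early genes shifted by 0.11 and TGF-beta and Wnt targets by 0.12, HIF targets and sphingolipid genes by -0.11 each, and G1/S genes by -0.11 (smallest adjusted p of these 0.152).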

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

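One setting, no background correction together with trend and robust, was chosen after seeing the data, and its tests with it. The cause of the changes below was not tested. Counts are of called genes in TCDD vs DMSO, CH223191 vs DMSO, the combination vs DMSO and the combination vs TCDD, in this order, where the reported counts were 0, 0, 0 and 4. They were 7, 8, 5 and 16 without background correction and with the authors' table, 4, 5, 5 and 7 with an offset of 50, 2, 7, 9 and 10 with trend and robust, and 9, 8, 7 and 14 with the added setting. The strict filter gave 2, 12 and 4 in the first 3 and no filter 1 in the second and 1 in the third. The average of probes gave 4 and array weights 1 in TCDD vs DMSO. In the combination vs TCDD, median scaling gave 2 and only the 2 groups compared 0. The overlap of TCDD and CH223191 responses was 1 gene without background correction, with the authors' table, the offset of 50, the strict filter and the added setting. Leaving out an array gave 0 to 1 in TCDD vs DMSO (1 without DMSO replicate 2 or TCDD replicate 2) and 0 to 6 in the combination vs TCDD (0 without TCDD replicate 1 or 3). The combination vs CH223191 and the interaction gave 0 in every setting run.

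The AhR battery in TCDD vs DMSO kept its call in 26 of 27 settings, at 0.17 to 0.38, and lost it under the strict filter (0.21). In the combination vs TCDD it was called in all 27, at -0.47 to -0.23. In CH223191 vs DMSO it was called at -0.113 without background correction, with the authors' table and with the added setting, at -0.114 with no filter and at -0.194 with trend and robust. Fry, which tests the members' own changes, also passed for the battery there (shift -0.194) and in the interaction (shift -0.249). Leaving out an array gave -0.207 to -0.184. NRF2 targets in CH223191 vs DMSO lost their call at -0.131 with only the 2 groups and with the estimated correlation, fry did not pass there either, and leaving out an array gave -0.146 to -0.114. In the combination vs TCDD they lost it with the estimated correlation (-0.167). The ATF4 list kept its calls against DMSO and against TCDD in all 27 settings, at 0.22 to 0.42.

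Directions turned for 6 genes, in differences that were not called over all genes. SLC7A5 in the combination vs DMSO was 0.035 with median scaling and 0.047 with cyclic loess, and -0.081 to 0.025 leaving out an array. ASNS there was -0.15 with the average of probes. Leaving out an array gave -0.018 to 0.092 for ALDH3A1 and -0.070 to 0.298 for HES1 with TCDD, -0.023 to 0.137 for CYP2S1 with CH223191 and -0.017 to 0.466 for NEDD9 in the combination vs TCDD. Of 77 gene results of at least 0.3, 48 were smaller by over 1.5 times without background correction (median share of the reported size 0.579) and 25 with the offset of 50. Of 2436 comparisons of 99 gene results, 2276 kept direction and side of the threshold, 129 passed newly, 19 no longer passed and 12 turned. Most of these results were not called to begin with, and only the 4 genes called in the combination vs TCDD could lose a call. The call was lost in 5 of 24 settings for TIPARP and in 4 of 24 for CYP1B1. For DUSP1 and for TRIB3 it was lost in 5 of 25 settings each.

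With the replicate number as a block, TCDD vs DMSO gave 1 gene and the AhR battery in CH223191 vs DMSO was called at -0.194. The numbers did not pair the arrays: of 18 same-number pairs 0 had deviations correlated over 0.1 (-0.164 to 0.059), and 2 of 12 arrays correlated best with their own number. A chip or section block was not run because the files used here give none. Signal over background limits genes near the detection limit, among them TIPARP and CYP1B1.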

Other observations

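Of the tests here, those of low DMSO arrays and of a single array behind the ATF4 list, and both tests on CYP1A1, were chosen only after the result was seen.

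In the combination against TCDD alone, further genes passed when adjusted over the list alone, though not over all genes. AXIN2, a feedback inhibitor of Wnt signalling, was lower (-0.74 ± 0.18, adjusted p = 0.0118) and ID1, a target of BMP signalling, higher (0.49 ± 0.14, adjusted p = 0.0166, and 0.0280 among short-lived transcripts). IRF1, a transcription factor of the interferon response, was lower (-0.63 ± 0.15, adjusted p = 0.00445), as were HPGD, which degrades prostaglandins (-0.47 ± 0.14, adjusted p = 0.0156), IER3 (-0.46 ± 0.13, adjusted p = 0.0301) and MUC1 (-0.53 ± 0.19, adjusted p = 0.0498). Without background correction AXIN2 was at -0.30, IRF1 at -0.37, HPGD at -0.25 and MUC1 at -0.18. IER3, ALDH1A3 and MUC1 were higher with TCDD and lower in the combination against TCDD. Both comparisons use the same TCDD arrays, so these values are not independent.

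The ATF4 list was higher with CH223191, with or without TCDD. DMSO arrays that were low for these genes are argued against by the combination against TCDD, which uses no DMSO array (adjusted p = 0.0103 with an estimated correlation). A single array is argued against by the highest adjusted camera p over the fits leaving out an array, 0.000393 at the preset correlation. Those fits were not run with an estimated correlation. Brightness of the list's genes is argued against by its percentile of 100 among 10000 random lists matched on expression. A stress response of the cells to CH223191 at this dose, through AhR or not, may be the source and was not tested apart from a difference in handling, for which the labels give no batch.

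CYP1A1 stayed at background with TCDD. TCDD arrays of cells without a response are argued against but not excluded. The battery rose in TCDD vs DMSO (camera adjusted p = 0.000333, but 0.0496 with an estimated correlation and 0.0593 under the strict filter). TIPARP was lower in the combination against TCDD (limma adjusted p = 0.00807), though its call was lost in 5 of 24 settings. TIPARP is a battery member and both comparisons use the same TCDD arrays. These results are therefore not independent, and TCDD arrays high for TIPARP by chance would favour both. That the probe does not report the transcript stays open, because the array has 1 probe for this gene.

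In 15 genes, 1 higher and 14 lower, all 3 treated groups differed from DMSO the same way at an unadjusted p under 0.01, among them MYH14 (-0.85, -0.86 and -0.94 with TCDD, CH223191 and the combination) and HDDC3 (0.56, 0.63 and 0.56), chosen after their values were seen. Of 100 assignments of the 12 arrays to groups, 3 gave as many, the real one included, against a median of 5 and a highest other of 16. The limit set beforehand was fewer than 5 of 100. The assignments mix arrays of different treatments, so treatment differences enter their spread and can lower their counts. Chance placement of the shared control is therefore made less likely but not excluded. DMSO arrays handled apart from the others, or an effect common to both compounds, may be the source, and the labels give no batch to test this.

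Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. In TCDD, CH223191 and the combination vs DMSO, and in the combination vs CH223191, the real count was 0, which all 10 splits reach by construction, with a highest other of 1, 0, 0 and 0. In the combination vs TCDD the real count was 4 and the highest other 0, and 1 of 10 splits, the real one, gave as many. For the interaction the real count was also 0, which all 100 assignments reach by construction, with a highest other of 1, so these counts of 0 decide nothing about chance. Each called list shift was reached by 1 of 10 splits, the real one. The real AhR battery shift was 0.36 with TCDD (highest other size 0.171) and -0.44 in the combination vs TCDD (0.227). The ATF4 list had 0.34 with CH223191 (0.141), 0.37 with the combination (0.157) and 0.34 in the combination vs TCDD (0.198). NRF2 targets had -0.13 with CH223191 (0.0736) and -0.17 in the combination vs TCDD (0.137).

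Of the 3427 detected probes without a usable gene name, limma called 0 in each of the 6 contrasts. A fit of all 13331 detected probes called 5 in the combination vs TCDD and 0 in the others.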
